A study of Mus musculus with 8 samples.

How the data were processed

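RNA of 8 libraries was measured by RNA sequencing. The cells were primary hepatic portal fibroblasts, sorted by their red fluorescent reporter (tdT) from the livers of normal mice that carry a Clec3b-driven, inducible Cre recombinase. Clec3b encodes tetranectin, and the reporter marks cells in which Cre was active. The sorted cells received a lentivirus carrying Klf4 (Lenti-Klf4, 4 libraries) or a control lentivirus (Lenti-Ctrl, 4 libraries). Per the labels, the libraries were made from polyadenylated RNA with a strand-marking second-strand step and sequenced in pairs. The time after transduction, the passage of the cells and whether the 4 libraries of a group came from separate mice are not stated.

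The authors deposited 1 table of raw counts per gene with 1 column per library, and in the same table the authors gave FPKM values, which are scaled by transcript length and library. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6 and DESeq2, the last with no version, and the mouse genome build GRCm39. They do not state how reads were counted, with which strand setting, or what was done with reads that match several genes. A second table by the authors holds a DESeq2 result with log2 fold changes of Lenti-Klf4 over Lenti-Ctrl as log2 values and, per the file headers, a p-value (pvalue) and an adjusted p-value (padj) for each gene. Gene coordinates are those of the deposited table. The count table held 32859 genes, and 106 gene IDs repeated the symbol of another ID.

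Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings, libraries were scaled by TMM factors, and Lenti-Klf4 was compared with Lenti-Ctrl by edgeR's quasi-likelihood F test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Normalised read counts (CPM) use the library totals multiplied by the TMM factors. Values are means ± SD over 4 libraries per group, fold changes are Lenti-Klf4 over Lenti-Ctrl, and SE is the standard error of the log2 fold change. For Klf4, Postn and Clec3b an exact two-sided permutation test of log2 CPM over the 70 splits of the libraries was run as well, with 0.1 CPM added. The smallest p that test can give is 0.0286. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound. That floor covers counting error only, since the reads carry no molecular identifiers.

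Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 30 lists. The lists cover fibroblast activation and matrix, markers of liver cell types, proliferation, signalling, inflammation, stress and metabolism. Each camera test was repeated with an estimated correlation, and fry was run as an alternative. GO terms of 15 to 200 tested genes were tested with camera in the same way, and that test was added after the data were seen.

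The gene lists, the tests, the alternatives (except those described as added) and the rule for naming genes were fixed before the data were examined. The rule named Klf4, Postn and Clec3b. Among changed genes with a mean of at least 5 CPM, no overlap between the groups and an official symbol, it took the 10 with the largest rise and the 10 with the largest fall. It also took the 5 most abundant changed genes past a log2 fold change of 1. From each list it took up to 4 members with the smallest adjusted p and up to 2 of the most abundant members not past 0.05. Some genes that the rule named are not reported here, and no others took their place. Any other gene is described as chosen after its values were seen.

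Alternatives were DESeq2's size factors in edgeR (RLE), library totals alone, Klf4 left out of the scaling, no filter beyond a total count above 0, a filter of 1 CPM in at least 4 samples, DESeq2 1.42.0, limma-voom with sample quality weights, limma on log2 FPKM with 1 or 0.1 added, a test against a log2 fold change of 1 (glmTreat), a block for the replicate number, and each library left out in turn. On simulated data with 200 of 18439 genes changed, the edgeR test recovered 22.5% of genes at a 1.2-fold change, 48.5% at 1.5-fold, 69.5% at 2-fold and 81.5% at 4-fold. It made 0, 3, 11 and 6 false calls in those runs. Drawings were made with matplotlib 3.10.9. Reads were not analysed here.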

Results

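The data were gene counts from 8 libraries of Clec3b-tdT⁺ portal fibroblasts, 4 with control lentivirus and 4 with Klf4 lentivirus. Total counts were 87361995, 62914436, 57306334 and 57787341 in Lenti-Ctrl replicates 1 to 4 and 82847723, 57950960, 61367261 and 60098618 in Lenti-Klf4 replicates 1 to 4. The libraries detected 22822 ± 728 genes in Lenti-Ctrl and 23475 ± 499 in Lenti-Klf4 (SD, n = 4 each). Mitochondrially encoded genes took 2.22 ± 0.0951% and 2.5 ± 0.0639% of counts, and the 10 most abundant genes took 7.09 ± 0.0600% and 4.70 ± 0.0163%. Across genes, which are not independent replicates, log2 CPM correlated between libraries with Pearson r of 0.978 to 0.983 within a group and 0.855 to 0.869 between groups. Principal component 1 held 80.9% of the variance and separated the groups, and component 2 held 3.75%. Libraries with the same replicate number were hardly more alike than others: their deviations from the group mean correlated at -0.005 to 0.022, against -0.032 to 0.017 for other pairs, so the test was not paired.

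The comparison asks how KLF4 affects the change of these portal fibroblasts into myofibroblasts, and the series title names periostin beside it. Klf4 encodes a zinc-finger transcription factor (ENSMUSG00000003032, chromosome 4, 55530603 to 55532453, minus strand). It was 2.61-fold higher in Lenti-Klf4, at 228 ± 17.9 CPM against 87.3 ± 3.82 CPM (SD, n = 4 each), with a log2 fold change of 1.38 (SE 0.0555, adjusted p = 2.5e-10 by edgeR's quasi-likelihood test). The 4 Lenti-Klf4 libraries held 201, 241, 234 and 235 CPM and the 4 Lenti-Ctrl libraries 86.8, 92.3, 83.0 and 87.1 CPM. The exact two-sided permutation test gave p = 0.0286, the smallest it can give. Whether these counts include RNA of the vector's Klf4 or leave out part of the gene is not given in the sources used here, so vector and endogenous RNA are not told apart. Postn encodes periostin, a matricellular protein of activated fibroblasts (ENSMUSG00000027750, chromosome 3, 54268530 to 54298458, plus strand). It was 4.38-fold lower in Lenti-Klf4, at 430 ± 14.5 CPM against 1885 ± 43.4 CPM, with a log2 fold change of -2.13 (SE 0.0294, adjusted p = 3.74e-14), and every Lenti-Klf4 library lay below every Lenti-Ctrl library (exact permutation p = 0.0286). Clec3b (ENSMUSG00000025784, chromosome 9, 122980011 to 122986497, plus strand), whose reporter defined the sort, was near the detection limit in both groups, with 4 counts over the Lenti-Ctrl libraries and 73 over the Lenti-Klf4 libraries. That is 0.0171 ± 0.0342 and 0.280 ± 0.174 CPM, below the filter of the edgeR test. The exact permutation test gave p = 0.0571 for Clec3b, or p = 0.0286 when scaled by library totals alone or without Lenti-Klf4 replicate 1, 3 or 4. With no filter, Clec3b passed at an adjusted p of 0.0208 in edgeR and 0.00337 in DESeq2.

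**Figure D1:**
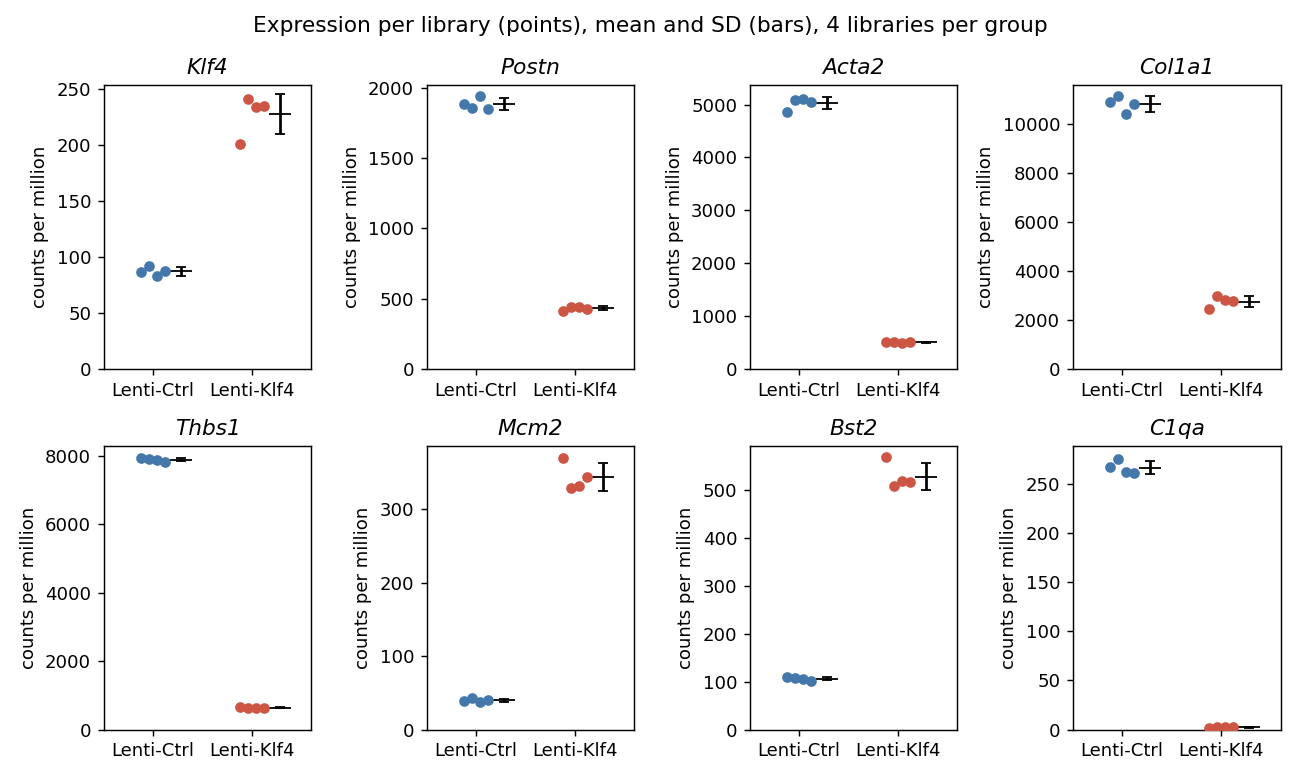
CPM of Klf4, Postn, Acta2, Col1a1, Thbs1, Mcm2, Bst2 and C1qa in each of the 8 libraries, with the mean and SD of each group as bars. Klf4, Mcm2 and Bst2 were higher in all 4 Lenti-Klf4 libraries than in any Lenti-Ctrl library, and the other 5 genes were lower in all 4.

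Expression differed across most of the transcriptome. Of 18439 genes tested, 13307 (72.2%) passed an adjusted p of 0.05, 6914 of them higher and 6393 lower in Lenti-Klf4, and 6284 of those also passed a log2 fold change of 1 in either direction (3016 higher, 3268 lower). The groups did not overlap for 12760 genes (69.2%), where chance gives 2.86%. These p-values and counts rest on the spread between libraries. Whether the libraries of a group came from separate mice is not stated. If they share 1 source, the p-values do not measure the spread between animals or cultures. Abundant genes past both thresholds included 4 matrix genes that were lower in Lenti-Klf4. Thbs1, a thrombospondin, was at 7889 ± 43.9 against 643 ± 9.59 CPM. Col1a1 was at 10815 ± 311 against 2749 ± 225 CPM, Col4a1 at 7068 ± 197 against 1381 ± 41.1 CPM and Sparc at 6210 ± 132 against 1555 ± 139 CPM. Scaling by library totals alone moved the log2 fold change of the median gene by 0.19 and gave 8328 genes higher and 5172 lower, and FPKM with limma gave 7097 higher and 3830 lower with 1 added, so changes are relative to the TMM scaling.

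The genes with the largest rise included several with no counts in any Lenti-Ctrl library. Ptn, encoding the growth factor pleiotrophin, was at 217 ± 14.1 CPM in Lenti-Klf4, at least 18028-fold higher. Also without counts in Lenti-Ctrl were Erdr1y, Erdr1x, Krt90, Ckmt1, Nlrp4e, Nol4 and Edn2, which lay between 10.6 and 62.9 CPM in Lenti-Klf4. Erdr1y and Erdr1x are close copies, so their shares of reads are uncertain. Dlk1, an imprinted gene and preadipocyte factor, rose from 0.628 ± 0.271 to 1297 ± 57.8 CPM, and Ifi202b from 0.179 ± 0.207 to 170 ± 17.5 CPM. Ifi202b has close paralogs. The largest falls included genes known from myeloid cells. Cx3cr1, Cd207, Clec4f and Il21r had 34.7, 23.5, 16.5 and 16.5 CPM in Lenti-Ctrl and no counts in Lenti-Klf4, which makes Cx3cr1 at least 3275-fold and Clec4f at least 1548-fold lower. Vsig4 fell from 163 ± 7.19 to 0.453 ± 0.164 CPM, C5ar1 from 60.4 ± 2.94 to 0.20 ± 0.101 CPM and Arg1 from 56.7 ± 3.76 to 0.268 ± 0.20 CPM, and Trem1, Ms4a6b and Pilra had log2 fold changes of -8.38, -8.09 and -7.47.

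**Figure D2:**
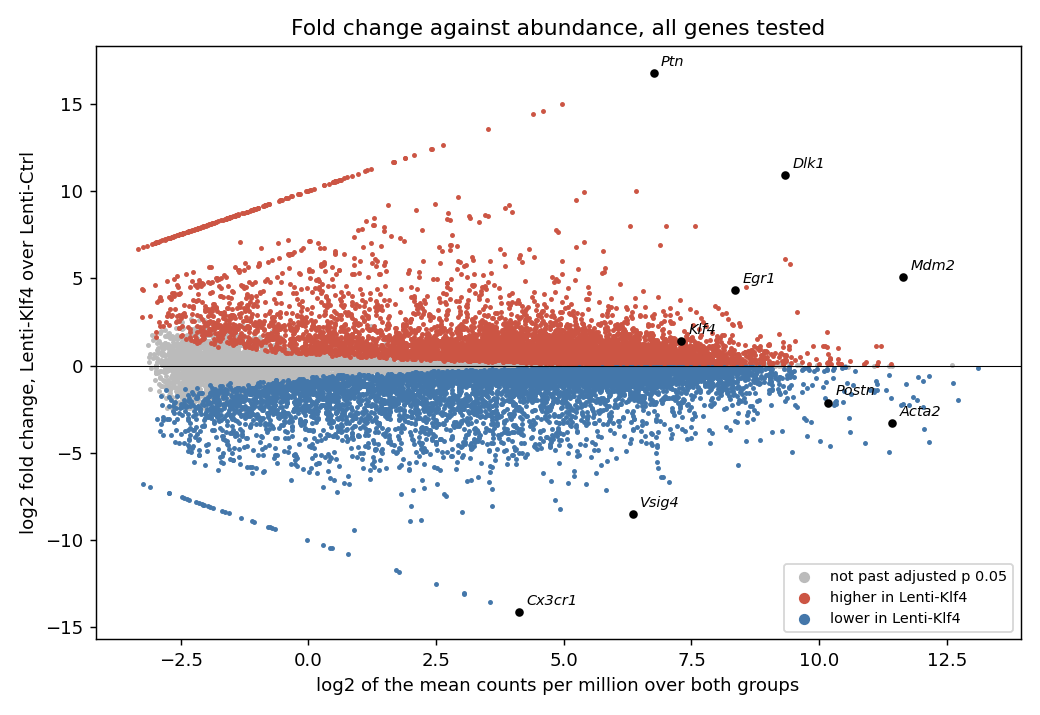
Log2 fold change of Lenti-Klf4 over Lenti-Ctrl for each gene tested (vertical axis) against the log2 mean CPM over the 8 libraries (horizontal axis), with selected genes labelled. Diagonal lines of points are genes with 0 counts in 1 group, whose fitted fold change is no bound, and the median gene lies at 0.03.

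Of 30 gene lists, 19 passed an adjusted p of 0.05 by camera, 6 towards higher and 13 towards lower expression in Lenti-Klf4. With an estimated correlation only the cholesterol synthesis list still passed. Counts of members below were the same when adjusted over the list alone, except where another count is given. Medians were the same with members that had no counts in 1 group set at their bound. In the same libraries, the macrophage and leukocyte markers summed to 5886 CPM in Lenti-Ctrl and 251 CPM in Lenti-Klf4.

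Contractile and collagen genes, which mark myofibroblasts, were lower in Lenti-Klf4. All 20 contractile and smooth muscle genes fell, with a median log2 fold change of -3.16 (adjusted p = 2.61e-10, and adjusted p = 0.0551 with an estimated correlation). Acta2, encoding smooth muscle actin, fell from 5027 ± 112 to 503 ± 3.84 CPM (log2 fold change -3.32, SE 0.0222), Tpm2 from 607 ± 16.7 to 64.5 ± 2.68 CPM, and Lmod1 from 117.5 ± 5.40 to 4.32 ± 0.285 CPM. Of 20 collagens, 17 fell, 2 rose and 1 did not pass (median -2.0, adjusted p = 2.66e-06, and adjusted p = 0.342 with an estimated correlation). Col6a3 fell from 680 ± 15.3 to 95.0 ± 3.54 CPM and Col5a2 from 5781 ± 65.3 to 1182 ± 63.2 CPM. Col8a2, which did not pass, was at 0.874 ± 0.0806 and 0.674 ± 0.181 CPM. Markers of macrophages and leukocytes moved the same way as these lists, with a median of -4.89.

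Matrix genes differed as well, most of them lower in Lenti-Klf4. Of 35 matricellular and elastic fibre genes, 24 fell, 10 rose and 1 did not pass (median -0.67, adjusted p = 0.00364, and adjusted p = 0.331 with an estimated correlation). Eln, encoding elastin, fell from 664 ± 25.9 to 12.9 ± 1.57 CPM and Ccn2, a growth factor-binding matrix protein, from 5158 ± 79.6 to 167 ± 20.2 CPM, and Comp was at 0.275 ± 0.240 and 0.758 ± 0.212 CPM (log2 fold change 1.42, adjusted p = 0.0963). Comp passed as higher with voom (2.36, adjusted p = 0.0213) and without Lenti-Ctrl replicate 1 (2.0, adjusted p = 0.0486). Of 20 matrix crosslinking and processing genes, 17 fell and 3 rose (median -1.06, adjusted p = 1.39e-04, and adjusted p = 0.180 with an estimated correlation). Lox and Loxl2, which crosslink collagen, fell, with log2 fold changes of -2.19 and -3.81, while Pcolce, an enhancer of procollagen processing, rose from 217 ± 9.71 to 696 ± 20.5 CPM. Of 26 matrix degradation genes, 16 fell, 7 rose and 3 did not pass (median -0.88, adjusted p = 0.00909, and adjusted p = 0.396 with an estimated correlation). Mmp14 fell from 1115 ± 7.81 to 321 ± 13.7 CPM and the inhibitor Timp1 from 876 ± 20.8 to 185 ± 14.8 CPM, while Mmp3 stood at 361 ± 4.56 and 374 ± 40.1 CPM (log2 fold change 0.0499, adjusted p = 0.488) and passed as higher without Lenti-Klf4 replicate 1 (0.11, adjusted p = 0.00431). Of 28 integrins and adhesion genes, 19 fell, 7 rose and 2 did not pass (median -0.60, adjusted p = 0.00339, and adjusted p = 0.360 with an estimated correlation). Itga5, a fibronectin receptor subunit, fell from 1530 ± 20 to 175 ± 4.17 CPM. C1qa, a macrophage gene, stood at 266 ± 6.35 and 2.62 ± 0.583 CPM in the same libraries.

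Most genes of TGF-beta and growth factor signalling were lower in Lenti-Klf4. Of 36 TGF-beta pathway and target genes, 27 fell, 7 rose and 2 did not pass (median -1.59, adjusted p = 2.10e-06, and adjusted p = 0.0551 with an estimated correlation). Ltbp2 fell from 1664 ± 37.3 to 173 ± 5.11 CPM, Pmepa1 from 666 ± 12.8 to 132 ± 2.57 CPM and Tgfbi from 174 ± 7.00 to 8.51 ± 0.570 CPM. Of 31 YAP and serum response targets, 23 fell, 7 rose and 1 did not pass (median -0.70, adjusted p = 2.79e-04, and adjusted p = 0.160 with an estimated correlation). Ankrd1 fell from 530 ± 6.98 to 46.3 ± 4.14 CPM, whereas the immediate early gene Egr1 rose from 31.2 ± 0.957 to 625 ± 10.6 CPM. Of 47 growth factors and receptors, 34 fell, 11 rose and 2 did not pass (median -1.11, adjusted p = 7.21e-05, and adjusted p = 0.272 with an estimated correlation). Egfr fell from 245 ± 6.20 to 38.4 ± 1.88 CPM and Fgf2 from 567 ± 18.0 to 43.1 ± 6.92 CPM, while Fgf7 rose from 4.71 ± 0.914 to 85.3 ± 3.05 CPM. The 30 Wnt pathway genes did not pass as a list (8 rose, 15 fell, 7 did not pass, median -0.22, adjusted p = 0.148), with 9 up and 15 down when adjusted over the list alone. Wnt5a and Frzb fell, with log2 fold changes of -1.85 and -2.33. The macrophage gene Csf1r, whose product is the receptor of the growth factor Csf1 and which was chosen after its values were seen, was at 226 ± 7.16 and 3.87 ± 0.849 CPM.

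**Figure D3:**
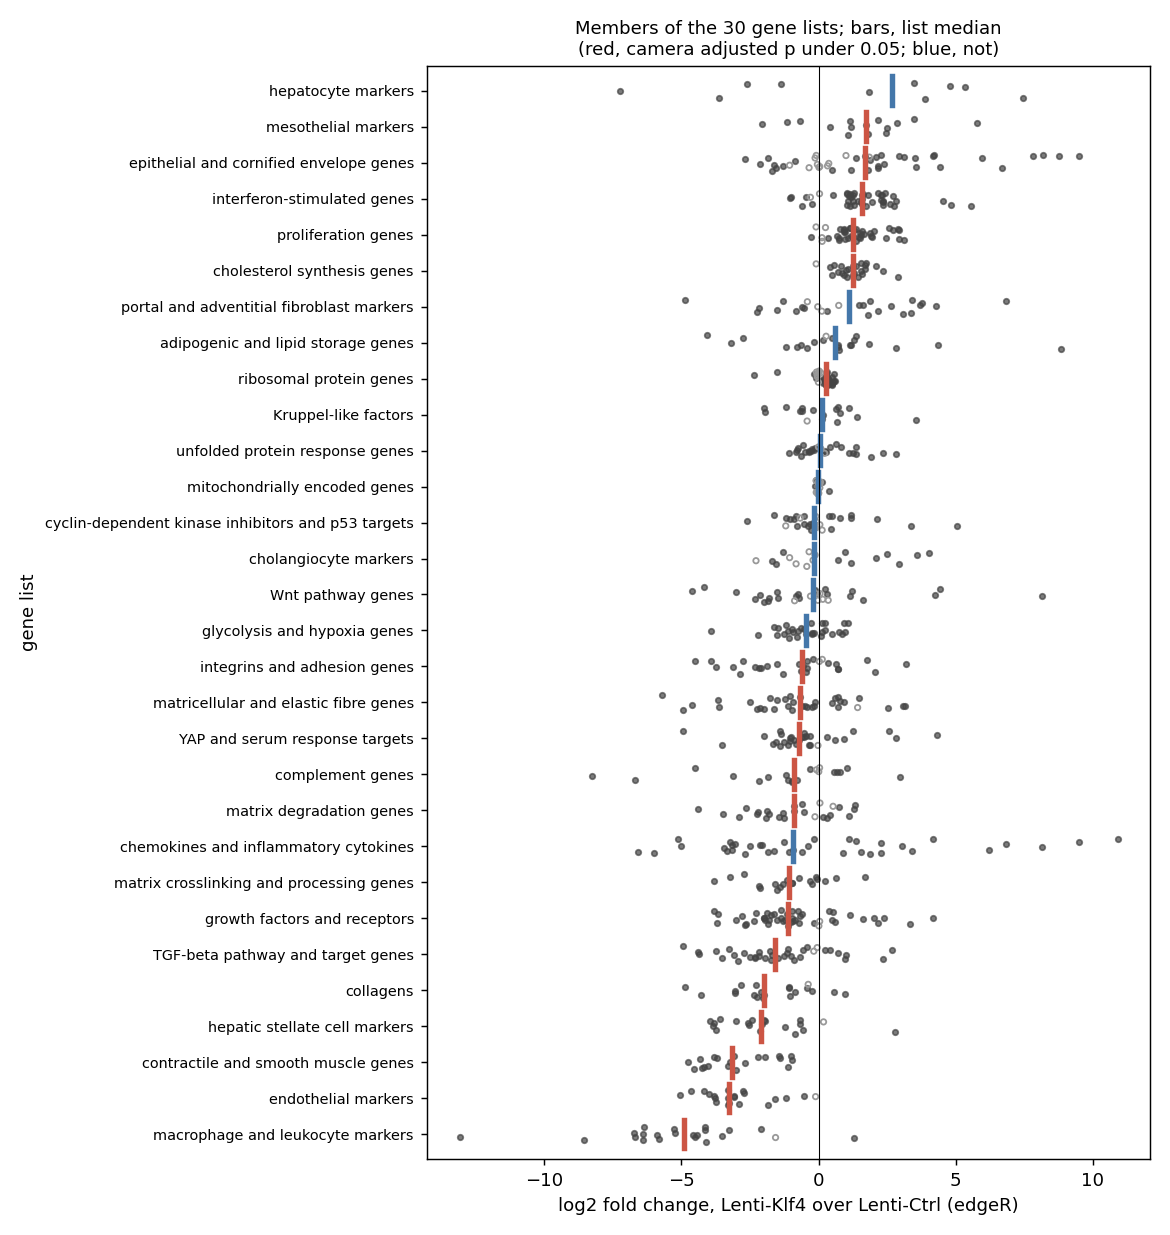
Log2 fold change of Lenti-Klf4 over Lenti-Ctrl (horizontal axis) for the tested members of each of 30 gene lists (vertical axis), filled where the member passed an adjusted p of 0.05 and open where it did not. Bars mark the list median, red for the 19 lists with an adjusted camera p under 0.05 and blue for the rest, and only the cholesterol synthesis list also passed with an estimated correlation.

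Markers of liver cell types moved apart. Of 26 portal and adventitial fibroblast markers, 14 rose, 8 fell and 4 did not pass (15 and 8 when adjusted over the list alone), with a median of 1.11 and no call for the list (adjusted p = 0.236). Ly6a, encoding the surface protein Sca-1, rose from 3.09 ± 0.478 to 39.8 ± 1.91 CPM and Slit2 from 38.6 ± 1.52 to 140 ± 2.35 CPM, Col15a1 fell from 93.5 ± 5.93 to 3.27 ± 0.671 CPM, and Entpd2 was at 4.71 ± 0.780 and 5.12 ± 0.632 CPM. Of 20 hepatic stellate cell markers, 18 fell, 1 rose and 1 did not pass (median -2.11, adjusted p = 6.39e-05, and adjusted p = 0.259 with an estimated correlation). Des, encoding desmin, fell from 214 ± 2.55 to 15.3 ± 1.61 CPM and Reln from 43.1 ± 0.822 to 3.23 ± 0.474 CPM, and Lrat was at 1.71 ± 0.390 and 1.95 ± 0.625 CPM. Of 15 mesothelial markers, 12 rose and 3 fell (median 1.73, adjusted p = 0.0114, and adjusted p = 0.396 with an estimated correlation). Msln, encoding mesothelin, rose from 63.2 ± 3.51 to 359 ± 8.15 CPM and Upk3b from 13.9 ± 0.557 to 101 ± 14.7 CPM. Of 21 endothelial markers, 20 fell and 1 did not pass (median -3.26, adjusted p = 5.63e-08, and adjusted p = 0.259 with an estimated correlation). Flt1, a VEGF receptor, fell from 170 ± 1.95 to 12.4 ± 1.08 CPM and Stab1, also expressed by macrophages, from 218 ± 2.55 to 6.67 ± 1.53 CPM.

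Macrophage and leukocyte markers had the lowest median of the 30 lists. Of 22 tested, 20 fell, 1 rose and 1 did not pass (1 up and 21 down when adjusted over the list alone), with a median of -4.89 (adjusted p = 1.01e-08, and adjusted p = 0.160 with an estimated correlation). C1qb fell from 244 ± 10.7 to 2.97 ± 0.507 CPM, C1qc from 237 ± 6.38 to 2.84 ± 0.486 CPM, and Laptm5, a gene of blood cells, from 259 ± 5.12 to 14.7 ± 1.70 CPM. S100a8 was at 0.915 ± 0.203 and 0.308 ± 0.223 CPM (adjusted p = 0.0616), and passed as lower in DESeq2 (adjusted p = 0.0346) and with voom (adjusted p = 0.0134). The 10 tested hepatocyte markers went both ways (6 rose, 4 fell), with a median of 2.67 and a mean of 1.2 while camera pointed down (adjusted p = 0.944). Trf, encoding transferrin, fell from 294 ± 4.22 to 24 ± 3.91 CPM and Apob from 41.0 ± 2.13 to 6.71 ± 1.2 CPM. The 18 cholangiocyte markers did not pass either (8 rose, 3 fell, 7 did not pass, adjusted p = 0.465), with a median of -0.16 and a mean of 0.45. Sox9 rose from 2.69 ± 0.287 to 32.2 ± 0.794 CPM and Krt7 from 13.2 ± 0.677 to 56.7 ± 7.10 CPM, while Cdh1 was at 5.67 ± 0.925 and 5.20 ± 0.456 CPM.

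Proliferation genes were higher in Lenti-Klf4. Of 40 genes, 35 rose, 1 fell and 4 did not pass (35 and 2 when adjusted over the list alone), with a median of 1.26 (adjusted p = 1.76e-09, and adjusted p = 0.180 with an estimated correlation). Mcm2, a subunit of the replicative helicase, rose from 39.9 ± 2.24 to 343 ± 18.9 CPM (log2 fold change 3.11, SE 0.0513) and Mybl2 from 8.46 ± 0.350 to 63.8 ± 2.38 CPM. Mki67, a marker of cycling cells, was at 91.5 ± 3.53 and 85.8 ± 3.25 CPM (log2 fold change -0.09, adjusted p = 0.0597). Its call depended on the setting: it passed as lower under the replicate block (adjusted p = 0.0408) and in DESeq2 (adjusted p = 0.0451), and as higher with library totals alone (log2 fold change 0.10, adjusted p = 0.0292). The macrophage gene C1qb moved the other way in these libraries, by -6.37 on the log2 scale. The 30 cyclin-dependent kinase inhibitors and p53 targets had no common direction (9 rose, 13 fell, 8 did not pass, adjusted p = 0.472), with a median of -0.16 and a mean of 0.06. Cdkn2a, a tumour suppressor locus, rose from 13.2 ± 1.12 to 135 ± 5.26 CPM and Gadd45a from 45.9 ± 3.26 to 199 ± 7.74 CPM, while Cdkn1a fell from 547 ± 0.893 to 177 ± 4.91 CPM. Mdm2, encoding the ubiquitin ligase of p53 (ENSMUSG00000020184, chromosome 10, 117524780 to 117546663, minus strand), rose 33.4-fold, from 187 ± 8.71 to 6235 ± 209 CPM (log2 fold change 5.06, SE 0.0396, adjusted p = 3.24e-16).

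The neighbours of Mdm2 were chosen after their values were seen. Slc35e3, a transporter gene beside Mdm2 (chromosome 10, 117569584 to 117582270), rose from 23.9 ± 1.36 to 1365 ± 20 CPM, a log2 fold change of 5.83. Cpm and Nup107, which flank this pair, rose by 2.05 and 1.12 on the log2 scale. Further out the genes went both ways, with log2 fold changes of 0.62 for Cpsf6, -0.64 for Rap1b, -0.68 for Frs2, and -4.44 and -3.25 for the lysozyme genes Lyz2 and Lyz1, but 1.41 for Mdm1 and 0.70 to 2.35 for a cluster of Cdc5lrt genes and pseudogenes. Other genes chosen after their values were seen also separated the groups in every library. Cwc22, a splicing factor gene, rose from 32.6 ± 1.72 to 731 ± 12.6 CPM. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had log2 fold changes of -2.21 to -1.73. Erdr1y, which the table also places on the Y chromosome, rose together with its close copy Erdr1x on the X chromosome.

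**Figure D4:**
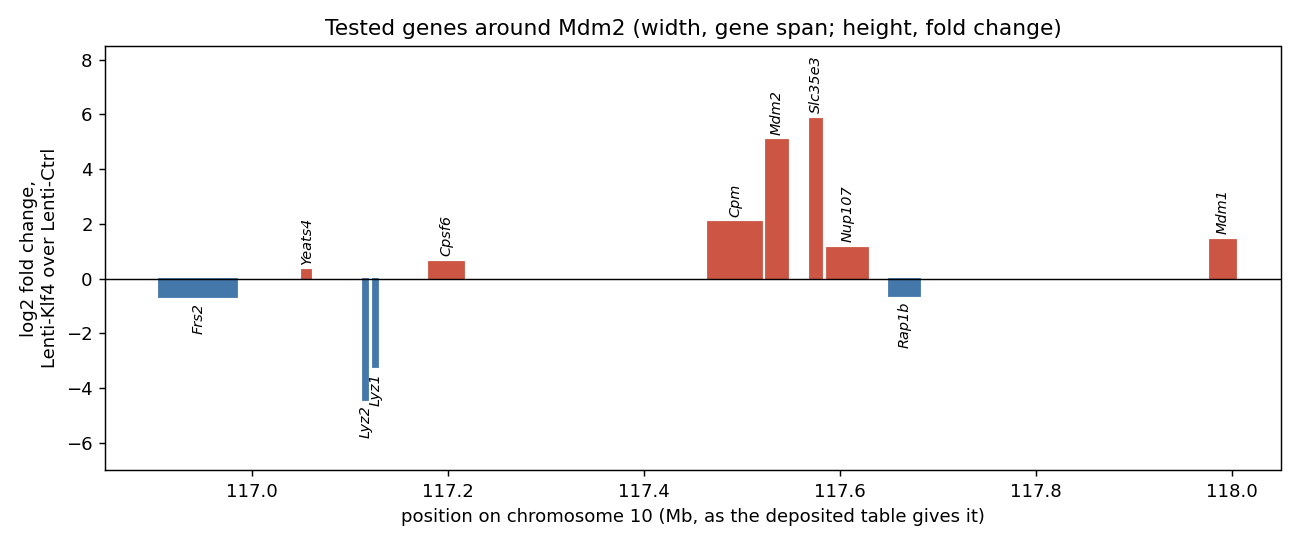
Log2 fold change of Lenti-Klf4 over Lenti-Ctrl (vertical axis) of genes along chromosome 10 around Mdm2 (horizontal axis, position in GRCm39). Mdm2 and Slc35e3 stand at 5.06 and 5.83, the other genes drawn lie lower, from 2.05 for Cpm to -4.44 for Lyz2, and the Cdc5lrt genes are not drawn.

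Transcription factor and epithelial genes were mixed. The 17 Kruppel-like factors had no common direction (9 rose, 7 fell, 1 did not pass, median 0.11, adjusted p = 0.834), with Klf5 rising from 3.85 ± 0.743 to 45.3 ± 3.59 CPM and Klf13 falling from 76.2 ± 4.30 to 19.1 ± 2.80 CPM. Of 43 epithelial and cornified envelope genes, 24 rose, 8 fell and 11 did not pass (median 1.71, adjusted p = 0.0199, adjusted p = 0.463 with an estimated correlation, and 0.0907 when scaled by library totals alone). Krt14, a basal keratin, rose from 0.382 ± 0.139 to 39.7 ± 5.49 CPM and Cgn, encoding the tight junction protein cingulin, from 1.0 ± 0.0924 to 18.1 ± 1.72 CPM, while Esrp2 fell from 21.0 ± 0.954 to 3.30 ± 0.417 CPM.

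Interferon-stimulated genes were higher in Lenti-Klf4. Of 44 genes, 37 rose, 5 fell and 2 did not pass (median 1.57, adjusted p = 3.27e-08, and adjusted p = 0.117 with an estimated correlation). Bst2, which tethers budding viruses, rose from 106 ± 3.44 to 527 ± 27.8 CPM, Stat2 from 50.1 ± 1.43 to 166 ± 5.14 CPM and Mx2 from 1.65 ± 0.364 to 76.2 ± 5.24 CPM. Both groups had received a lentivirus, and the macrophage gene Laptm5 had a log2 fold change of -4.14 between them. The 37 chemokines and inflammatory cytokines went both ways (15 rose, 22 fell), with a median of -0.92 and a mean of 0.11 (adjusted p = 0.236). The neutrophil chemokines Cxcl5 and Cxcl1 rose from 0.0974 ± 0.0787 to 75.9 ± 6.32 CPM and from 0.570 ± 0.0752 to 42.3 ± 6.18 CPM, while Csf1, the macrophage growth factor, fell from 2295 ± 33.9 to 543 ± 13.3 CPM. Of 20 complement genes, 12 fell, 5 rose and 3 did not pass (median -0.88, adjusted p = 0.0488, and adjusted p = 0.482 with an estimated correlation). C3 rose from 62.7 ± 3.59 to 486 ± 18.9 CPM, while C1qa, which macrophages express, fell. The complement call was lost with RLE scaling (adjusted p = 0.0540), the 1 CPM filter (0.0745), the replicate block (0.0541), and without Lenti-Ctrl replicate 2 (0.0521) or Lenti-Klf4 replicate 1 (0.0521).

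Cholesterol synthesis genes rose nearly as a whole. Of 25 genes, 24 rose and 1 did not pass (24 up and 1 down when adjusted over the list alone), with a median of 1.26 (adjusted p = 1.92e-08, and adjusted p = 0.0278 with an estimated correlation). Acat2 rose from 21.3 ± 0.659 to 159 ± 5.85 CPM, Insig1, a sterol sensor, from 61.3 ± 2.28 to 309 ± 8.94 CPM and Fdft1, encoding squalene synthase, from 51.9 ± 1.88 to 153 ± 1.75 CPM. Beside this rise, the macrophage gene C1qc had a log2 fold change of -6.40. The 22 adipogenic and lipid storage genes did not pass as a list (13 rose, 8 fell, 1 did not pass, median 0.60, adjusted p = 0.336). Pparg, the regulator of fat cell differentiation, rose from 4.18 ± 0.529 to 29.7 ± 2.07 CPM, while Cd36 and Apoe, which macrophages also express, fell, with log2 fold changes of -3.21 and -4.06. The 31 glycolysis and hypoxia genes were split (11 rose, 20 fell, median -0.46, adjusted p = 0.0622, but 0.0445 without Lenti-Ctrl replicate 3 and 0.050 without Lenti-Ctrl replicate 4). Pgk1 rose from 725 ± 17.1 to 1543 ± 61.7 CPM and Slc16a3, a lactate transporter, fell from 260 ± 10.8 to 17.0 ± 3.92 CPM.

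The remaining lists concern protein synthesis and mitochondria. The 28 unfolded protein response genes had no common direction (12 rose, 13 fell, 3 did not pass, median 0.04, adjusted p = 0.834), with Chac1 rising from 19.5 ± 1.37 to 140 ± 5.27 CPM and Ddit3 from 59.4 ± 2.72 to 153 ± 2.69 CPM. Of 40 ribosomal protein genes, 28 rose, 4 fell and 8 did not pass (median 0.27, adjusted p = 0.00490, and adjusted p = 0.482 with an estimated correlation). Rpl5 rose from 533 ± 16.8 to 779 ± 14.9 CPM. Rps2 fell from 1268 ± 31.2 to 247 ± 44.1 CPM, and it has many pseudogenes that could share its reads, which was not tested. The 13 mitochondrially encoded genes did not pass as a list (2 rose, 2 fell, 9 did not pass, median -0.02, mean 0.01, adjusted p = 0.944). Their members near 0 turn direction with scaling: mt-Co1 had a log2 fold change of -0.12 with TMM and 0.07 with library totals alone, and mt-Co2 of -0.08 and 0.11. mt-Co2 also did not pass with no filter (adjusted p = 0.123) or without Lenti-Klf4 replicate 4 (0.0542).

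The authors' own DESeq2 table of the same comparison held 11361 genes. It lists 722 genes as higher and 886 as lower, which are exactly the genes with a fold of at least 2.5 and an adjusted p under 0.01, and all 1608 passed 0.05 in edgeR. Over 11343 genes in both, log2 fold changes correlated across genes, which are not independent replicates, with Pearson r of 1.0, and 95.2% had the same sign. All 11335 unique symbols of the table had an FPKM of at least 1 in at least 5 of the 8 libraries, and 0 symbols outside it did. A gene expressed in 1 group alone cannot meet that. Of 1426 unique symbols with an FPKM of at least 1 in exactly 4 libraries, 663 had it in all 4 Lenti-Ctrl and no Lenti-Klf4 library and 691 the reverse. Of the 1426 symbols, 1411 were tested here, of which 683 rose, 672 fell and 1123 passed the authors' fold and adjusted p. They include Dlk1, Ptn, Csf1r and Stab1, and also Cdsn, a gene of cornified epithelium that rose from 1.01 ± 0.444 to 257 ± 13.1 CPM and was named after its values were seen. With the authors' fold and adjusted p, edgeR called 4427 genes (2047 higher, 2380 lower), 2784 of them outside the authors' table. For Klf4 itself the authors' table gave a log2 fold change of 1.59, against 1.38 in edgeR, while over all genes the table differed from edgeR by a median of -0.08. Klf4 was also the 1 unique symbol of 11335 whose mean in the authors' table (10438) differed from the mean of the scaled deposited counts (10097) by more than 0.02 on the log2 scale. The level of Klf4 thus depends on which deposited table is read. Its gene span in the count table was 1851 bases.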

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

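All tests of explanations in this part were chosen after the results they address were seen, while the splits of the libraries were planned for the changed genes and the gene lists and added with the GO terms.

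Macrophage and leukocyte markers were lower in Lenti-Klf4, with a median log2 fold change of -4.89 over 22 tested genes of a list fixed beforehand, of whose 30 members 1 is also in another list. The sort by the tdT reporter should remove such cells, yet Lyz2 was at 3659 ± 134 CPM, C1qa at 266 ± 6.35 CPM and Laptm5 at 259 ± 5.12 CPM in Lenti-Ctrl, against 169 ± 25.3, 2.62 ± 0.583 and 14.7 ± 1.70 CPM in Lenti-Klf4. Scaling cannot account for it, since the median was -4.70 with library totals alone. Macrophage RNA in the Lenti-Ctrl libraries is a candidate explanation, with 20 of the 22 genes lower (21 when adjusted over the list alone). Cd74 rose and the others fell by unequal ratios. That does not decide against it, since other cells in these libraries may express some of these genes. The levels of Lyz2, C1qa and Laptm5 in Lenti-Ctrl, which received no Klf4 lentivirus, are themselves no response to it. Fewer macrophages, another origin of the Lenti-Klf4 cells and a response of the cells to Klf4 cannot be told apart, since each could lower the list.

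Mdm2 and Slc35e3, Cwc22 with its copies and Ifi202b were higher in every Lenti-Klf4 library, and the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower. Erdr1y, also placed on the Y chromosome, was higher, but so was its close copy Erdr1x on the X chromosome. Their shares of reads are uncertain, so Erdr1y does not bear on the fall of the 4 Y-linked genes. A p53 response behind the Mdm2 rise was not decided. The other 29 genes of the p53 list went both ways (median -0.22), with Cdkn1a at -1.63, Gadd45a at 2.12 and Trp53 at 1.17. That list also holds cyclin-dependent kinase inhibitors, so its median is a weak measure of p53 activity. Slc35e3, which lies beside Mdm2, rose by 5.83 on the log2 scale, more than Mdm2 at 5.06. Reads shared among the 8 Cwc22 genes cannot account for the rise of their sum, which went from 33.0 ± 1.79 to 885 ± 14.5 CPM, a log2 ratio of 4.74. How that rise divides among the 8 genes is not settled, since the treatment of reads that match several genes is not stated. The median log2 fold change was -0.02 on chromosome 10, 0.03 on chromosome 1 and 0.22 on chromosome 2 (SD of single genes at most 1.57). A gain of the whole chromosomes that hold the higher genes therefore does not account for these rises of 4.48 to 10.02. The comparison asks only about rises of that size and does not bear on a smaller gain of these chromosomes. Local gains of DNA, another origin of the cells and an effect of Klf4 on these genes stay open, and no DNA was analysed here.

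Contractile, collagen and TGF-beta genes were lower in Lenti-Klf4, with list medians of -3.16, -2.0 and -1.59. RNA of other cells in Lenti-Klf4 would have to make up 88.8% of the RNA to lower the median contractile gene this far by dilution. The 3 medians were unequal, and of 26 portal and adventitial fibroblast markers 14 rose and 8 fell (median 1.11). That list did not pass by camera (adjusted p = 0.236), and its summed CPM was 7276 in Lenti-Ctrl and 5349 in Lenti-Klf4. Of the mesothelial genes 12 of 15 rose, and of the epithelial genes 24 of 43. These values do not decide on dilution, since such cells may express genes of these lists. Cells of another origin in the Lenti-Klf4 libraries cannot be told apart from the effect of the vector, since such an origin would coincide with the vector. The Cwc22 genes summed to at least 24.7 times more in each Lenti-Klf4 library than in any Lenti-Ctrl library. They were chosen because they separated the groups, so that ratio decides nothing. A response to KLF4, which the design names, stays open beside another origin of the cells and was not tested separately. RNA of other cells in the Lenti-Ctrl libraries was not tested for these 3 lists either. Of 20 hepatic stellate cell markers 18 fell and 1 rose (median -2.11). Of 21 endothelial markers 20 fell and 0 rose (median -3.26).

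Over 11087 genes, the chromosome medians of log2 fold change ran from -0.12 on chromosome 9 to 0.33 on chromosome 8. Their SD was 0.156 against at most 0.0736 in permutations within expression deciles (permutation p = 1e-04, the smallest they can give). The permutations treat genes as independent, so neighbours that change together would also raise the SD. No cause is drawn from it.

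Chance is excluded for changed genes and for genes past a log2 fold change of 1 only as far as 35 splits allow. The smallest share they can give is 1 in 35, and every other split mixed the groups, which adds their difference to the spread. Of the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many changed genes (13307, highest other 1), genes past a log2 fold change of 1 (6284, highest other 1), gene lists (19, highest other 18) and GO terms (314, highest other 231). For lists and terms the other splits were not empty. Those that kept 3 libraries of a group together gave 13 to 18 lists and 96 to 231 GO terms. With an estimated correlation 0 GO terms passed for the real split, so chance is not taken as excluded for their number. The margin for lists was 1, and the real split gave 18 with RLE, library totals, the 1 CPM filter or the block, where other splits were not counted, so chance is not taken as excluded for the number of lists.

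Of 358 groups of 4 values examined, 24 had a library whose gap to the nearest other, divided by the range of the group, exceeded Dixon's 95% critical value, where chance gives about 1 in 20, or 17.9. Of these, 14 were in Lenti-Klf4 replicate 1, which was the deepest of its group at 82847723 counts against 57950960 to 61367261 (0.863). In that library the ratio was 0.924 for Thbs1, 0.838 for Ccn2, 0.847 for Mmp14, 0.918 for Sema3c, 0.842 for Apob, 1 for Apoc1, 0.912 for Mcm5, 0.911 for Cdkn2a, 0.972 for Cxcl5, 0.882 for Ero1a, 0.836 for Frzb, 0.865 for Wnt2 and 0.974 for Rpl10a. Apoc1 had counts in that library alone among the Lenti-Klf4 libraries. Lenti-Klf4 replicate 2 stood apart for Acat2 (0.849) and Rpl5 (0.849), and Lenti-Klf4 replicate 4 for Klf7 (0.888). Among the Lenti-Ctrl libraries, replicate 1 stood apart for Il21r (0.982), replicate 2 for Clec3b (1, the library that held all 4 counts), and replicate 4 for Col8a2 (0.830) and Oasl2 (0.848). Lenti-Ctrl replicate 3 stood apart for Ecm1 (0.858), Frzb (0.914) and mt-Co3 (0.839).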

How the results depend on the processing

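The authors' thresholds applied to edgeR and the GO test with an estimated correlation were chosen after the data were seen, and the other alternatives were planned. Klf4 stayed higher and Postn lower, past the threshold, under every alternative that tested them, with log2 fold changes of 1.33 to 1.43 and -2.17 to -2.12 when 1 library was left out. Leaving out 1 library gave 13039 to 13188 changed genes (6604 to 6917 higher, 6158 to 6533 lower), 6191 to 6433 past a log2 fold change of 1, and 18 to 20 lists. Changed genes numbered 14069 with DESeq2, 13728 with voom, 13292 with RLE, 13500 with library totals, 13604 with no filter, 11904 with the 1 CPM filter and 12918 with the replicate block. Limma on FPKM gave 3830 genes lower and 3131 past 1 with 1 added, and 3817 and 4171 with 0.1 added, where fewer genes (12804) were tested. The test against a log2 fold change of 1, which asks for a larger change, gave 4674 genes. The authors' thresholds on edgeR gave 4427. They ask for a fold of 2.5 and also for an adjusted p under 0.01, and the 2 were not separated. In the authors' table an adjusted p under 0.05 held for 9219 genes and 2631 of those passed 1, against 1608 listed.

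Clec3b had a log2 difference of 1.6 with TMM, 1.68 with library totals, 3.93 in edgeR with no filter and 4.04 in DESeq2, and 1.33 to 1.93 with 1 library left out (permutation p 0.0286 to 0.0857). Voom, FPKM, the 1 CPM filter and the block gave no value for it. Among lists, 1 passed with an estimated correlation, 28 by fry's directional test and 30 by its mixed test, which asks another question. The cyclin-dependent kinase inhibitors and p53 targets turned to up in fry's directional test (adjusted p = 1.24e-05). With an estimated correlation 0 of 1433 GO terms passed camera, and 202 had an unadjusted p under 0.05.

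Of 136 named genes that passed, 134 to 136 still did under each alternative except the test against a log2 fold change of 1 and the authors' thresholds, for which they were not counted. Mki67 also passed as lower with RLE (adjusted p = 0.0176), the 1 CPM filter (0.00686), voom (0.0266), and without Lenti-Ctrl replicate 4 (0.0224) or Lenti-Klf4 replicate 1 (0.0119), and S100a8 without Lenti-Klf4 replicate 3 (0.0170) or 4 (0.0452). Ltbp3 passed as lower with RLE (0.0246), the 1 CPM filter (0.00866) and without Lenti-Klf4 replicate 2 (0.0260), and Isg20 without Lenti-Klf4 replicate 2 (0.0148) and Trp53inp1 without Lenti-Ctrl replicate 2 (0.0466). Itga3 passed as higher without Lenti-Klf4 replicate 1 (0.0164) and with voom (0.0364), and Plk1 without Lenti-Ctrl replicate 3 (0.0368). Of the named genes that did not pass, 12 others, among them Mmp3, Itga3 and Plk1, passed as higher with library totals, and Entpd2 did on FPKM (0.0442 with 1 added). Genes near 0 turned positive with library totals: Ltbp3 0.14, Mki67 0.10, Canx 0.19, Ajuba 0.17, Rpl13 0.19, mt-Co1 0.0696, mt-Co2 0.11 and mt-Cytb 0.17. In the same order, limma on FPKM gave 0.14, 0.0948, 0.19, 0.17, 0.19, 0.0742, 0.11 and 0.18 with 1 added, and 0.15, 0.11, 0.19, 0.17, 0.19, 0.0742, 0.11 and 0.18 with 0.1 added. Both leave out the TMM factors, which move the median gene by 0.19 on the log2 scale. Of all genes called with TMM, 53 were called the opposite way with library totals, 55 with each FPKM setting and 0 with each other setting in which this was counted, which leaves out the same 2. A simulated 1.5-fold change was recovered in 48.5% of genes, but with 200 of 18439 genes changed, against 13307 called here. The adjustment of p-values depends on that share, so the simulated recovery does not measure the power in these data. Depth and the number of libraries were not varied. Genes not past the threshold are not taken as unchanged. The cause of the other differences was not tested.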

Other observations

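The GO terms described here were tested only after the gene results were seen. Of 1433 terms, 179 were called towards higher and 135 towards lower expression in Lenti-Klf4 by camera with the preset correlation, and 0 with an estimated correlation. Genes of RNA processing and protein synthesis were higher. Of 104 ribosome biogenesis genes, 89 rose and 8 fell (median log2 fold change 0.72, adjusted p = 1.61e-09, and adjusted p = 0.350 with an estimated correlation). Of 169 genes of the spliceosomal complex, 137 rose and 13 fell (median 0.52), and of 41 aminoacyl-tRNA ligase genes 33 rose and 1 fell (median 0.71). All 23 genes of DNA replication initiation rose, with a median of 2.14 (adjusted p = 1.45e-08, and adjusted p = 0.350 with an estimated correlation).

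Lower terms included angiogenesis, where 84 of 115 genes fell and 19 rose (median -0.80, adjusted p = 8.01e-07, and adjusted p = 0.350 with an estimated correlation), and the Z disc of muscle, where 56 of 83 fell and 13 rose (median -0.81). In the same libraries 20 of 21 endothelial markers fell (median -3.26) and macrophage and leukocyte markers had a median of -4.89. Of 19 genes of chondroitin sulfate biosynthesis, which builds chains of matrix proteoglycans, 17 fell and 2 rose (median -1.04, adjusted p = 3.82e-04, and adjusted p = 0.350 with an estimated correlation). Some genes were chosen after their values were seen. Trp53 rose from 99.7 ± 4.66 to 224 ± 9.48 CPM and the chromatin gene Hmga2 from 102 ± 6.07 to 527 ± 23.0 CPM. The imprinted genes H19 and Igf2 fell from 55.2 ± 5.07 to 4.27 ± 0.368 CPM and from 54.5 ± 4.47 to 19.2 ± 3.08 CPM, while the imprinted gene Dlk1 rose. Xist, the X-inactivation RNA, had 12 counts over the Lenti-Ctrl libraries and 53 over the Lenti-Klf4 libraries.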
